A study of Homo sapiens with 6 samples.

How the data were processed

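Gene expression was measured on 6 deposited two-colour arrays, each carrying Cy5-labelled RNA of cells given SU11274 at 10 µM for 6 h and Cy3-labelled RNA of untreated cells of the same line, with 3 arrays labelled RPMI8226 and 3 labelled RPMI8226/R5. Dyes were not swapped, so a dye effect is part of every treated-to-untreated ratio and cancels only in the difference between the lines. Per the labels' protocols, SU11274 was dissolved at 10 mM in DMSO and total RNA was amplified and coupled to the dyes by an aminoallyl method.

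Per the file headers, each array's file gives the mean raw intensity and the background-corrected net intensity of each spot in both channels, and the deposited series values are the ratio of net Cy5 to net Cy3. Per the series' design text, the authors removed a fitted polynomial background, normalized the channels by loess and took logarithms. The deposited ratio is on a linear scale, with a median between 0.894 and 0.985 over the arrays. Median net intensities of gene probes were close between the channels on every array. On RPMI8226 replicate 1 they were 257.9 in Cy5 and 257.7 in Cy3, where the raw medians were 1544 and 201. The net values were thus balanced between channels and not only background-corrected. The step that did this is not given in the sources used here. The ratio column of each array's file matched both series-wide tables in 100% of rows within a relative tolerance of 1e-05. Ratios of 99999 and 0.00001 stand in for spots with no usable ratio; a ratio was set missing wherever a net intensity was 0 or less, which removed between 0.161% and 19.1% of gene probes per array. The background standard deviations in the files are 0 throughout.

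Each array holds 39200 spots, of which 30968 are gene probes, 7156 are labelled empty and 1076 are other controls. The files pair 19222 probes with 1 gene name, 505 with several and 11241 with none; older names were updated through a RefSeq table of GRCh38.p14, and no gene was named from a probe with several. No coordinates are given, because the files name no genome build.

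The arrays were compared before averaging. The arrays labelled RPMI8226 replicate 1 and RPMI8226/R5 replicate 1 held identical raw values at 95.9% of spots in Cy5 and 97.5% in Cy3, against at most 0.00765% and 0.0102% in the other 14 pairs. They were treated as one scan, counted once, as RPMI8226 replicate 1. This departs from the planned design, which used all 6 arrays, and leaves 5 distinct scans, 3 for RPMI8226 and 2 for RPMI8226/R5. The deposited labels do not settle which line that scan belongs to; the file of each of the pair names the same slide. Counting the scan once was decided after the data had been seen. The planned set of all 6 arrays was then kept as an alternative, and a fit with the scan counted as RPMI8226/R5 was added.

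Raw intensities were background-corrected by normexp with an offset of 50, fitted on all spots, and normalized by global loess within each array with control and empty spots at weight 0, using limma 3.58.1 in R 4.3.3. A probe was tested if it exceeded the 95th percentile of the empty spots in at least 1 channel on at least 3 arrays. This kept 1014 of 30968 gene probes. The same rule was met by 289 of 7156 empty spots, a larger share, so meeting it does not mark a probe as detected above background. One mean log2 ratio per line was fitted with limma's lmFit and eBayes, and each line's mean and the difference between lines were tested with Benjamini-Hochberg adjustment at 0.05. Each SE given is limma's moderated one, from a spread pooled over both lines and drawn toward that of the other probes. It does not measure the scatter of a line's own arrays. Untreated cells of both lines were compared in the Cy3 channel after Aquantile normalization between arrays. The filter left at most 2 measured members in any of the 28 gene lists, below the minimum of 5, so lists, and the genes named from them, were tested on all gene probes, 1 probe per gene of highest mean intensity, with camera at a preset correlation of 0.01; this is also a departure. Empty spots were tested in the same models of the ratios as a control, but not in the comparison of untreated lines. The 289 that met the brightness filter were also tested separately, which was added after the data had been seen. The separate-channel fit used an intraspot correlation of 0.536, and its estimation reached the iteration limit for some probes.

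The rule for named genes took, per comparison, up to 8 probes per direction past the threshold with one direction on all arrays, or the 5 of smallest unadjusted p where none passed; up to 4 members per list; and always MET, HGF, ABCB1, SDC1 and FNTB. Of the list members, those with an unadjusted p under 0.01 were printed, a limit set after the data had been seen, except 1 that is not reported here; members that passed when adjusted over the list alone were added. The lists, the tests and most alternatives were fixed before the data were examined. Scripts were tested on simulated arrays of independent normal noise, at each probe's spread from the fit of all gene probes. That spread can be smaller than in the fit of the 1014 probes. For HSPA6 in RPMI8226/R5 the SE was 0.281 against 0.393. Arrays here also share structure that the simulation lacks, so the shares recovered may be too high. Of 200 probes changed by 1 log2 unit in RPMI8226 among 1014 probes, 85.5% were recovered, and 100% of those changed by 2; for the difference between the lines the shares were 8% and 98.5%. Among all gene probes the shares were 54.5% and 100% in RPMI8226, and 0% and 93.5% for the difference. For the comparison of untreated lines, on simulated values with one spread for all probes, 96% of probes changed by 2 were recovered. In 100 simulations of camera on 5000 genes, a list of 20 genes shifted by 0.5 was found in 100, and an unshifted one in 3. These used one spread for all genes, no correlation between genes and an unadjusted p under 0.05.

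The alternatives were no background correction, median centring, the deposited ratios, no filter, array weights, an intensity trend, a replicate block, leaving out each array, and fits of 1 line alone, with further ones for the untreated lines and the lists. Removal of spatial trends with a running median over 15 by 15 spots was added after the data had been seen. The number of arrays limits the precision. Local brightness was log2 raw intensity minus such a running median (Python 3.11.15, SciPy 1.17.1).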

Results

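RPMI8226 is a human multiple myeloma cell line, and RPMI8226/R5 is a multi-resistant line derived from it. Gene expression was measured after exposure to SU11274, an inhibitor of the kinase of MET, the receptor for hepatocyte growth factor. Cells at 500000 per ml were given SU11274 at 10 µM for 6 h, and treated (Cy5) and untreated (Cy3) RNA of each experiment shared an array. The series holds 3 arrays per line, labelled as distinct experiments. One scan appeared under both lines, with 95.9% of raw Cy5 values identical, and was counted once, giving 3 arrays for RPMI8226 and 2 for RPMI8226/R5.

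Signal over background was low in every scan. Median raw intensity of gene probes ranged from 286 to 2409 in Cy5 and from 137 to 711 in Cy3, while spots labelled empty had medians from 301 to 2497 and from 139 to 744. Both arrays numbered 3 were the dimmest, with Cy5 medians of 286 in RPMI8226 and 315 in RPMI8226/R5, against 1544 or more on the other scans. Between 3.29% and 4.87% of gene probes exceeded the 95th percentile of the empty spots in a channel, where 5% would do so if the distributions were equal. A randomly chosen gene probe was brighter than an empty spot with a probability between 0.456 and 0.499, or between 0.462 and 0.522 on net intensity. Probes labelled as ribosomal protein genes, which are abundantly transcribed in growing cells, had a median local brightness at the 50.9th percentile of gene probes (63 probes), and probes labelled as olfactory receptors, which are restricted mainly to olfactory tissue, lay at the 51.8th (52 probes). In contrast, Cy3 control spots had Cy3 medians between 19184 and 30001. The gene names below are therefore the labels of the spots, and gene probes as a set could not be separated from background, although single spots were far brighter on some arrays, as for ATP8B2 in Cy3.

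**Figure D1:**
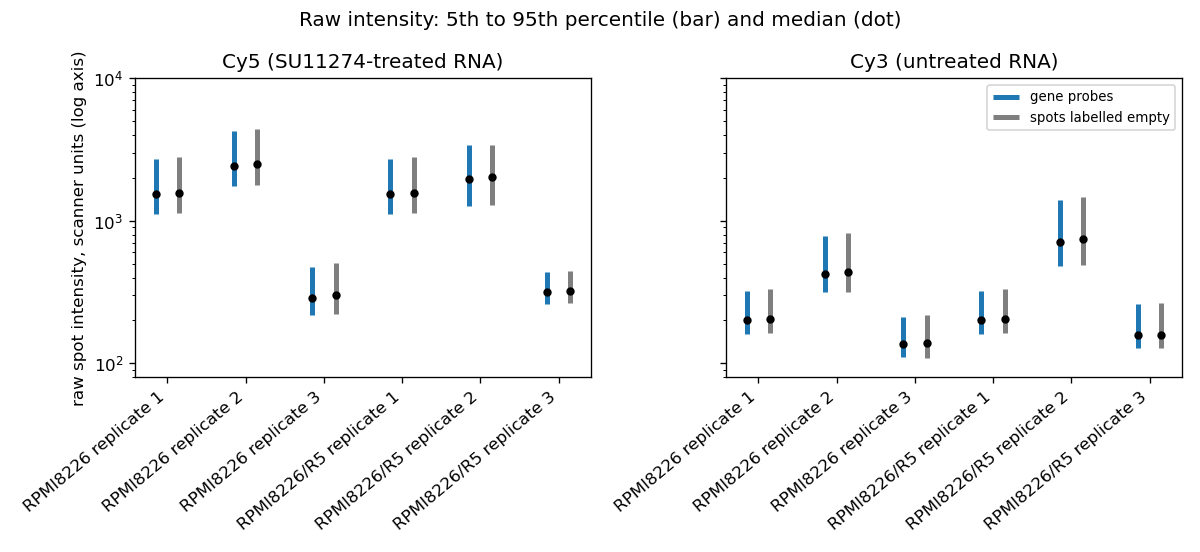
Raw spot intensity (log axis) per deposited array in Cy5 and Cy3. Bars span the 5th to 95th percentile and dots mark the median of all gene probes (blue) and of 7156 spots labelled empty (gray), which overlap on all 6 arrays; RPMI8226 replicate 1 and RPMI8226/R5 replicate 1 are the same scan.

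The first comparison asked which genes responded to SU11274 in RPMI8226. The probe labelled ATP8B2, a phospholipid-transporting ATPase subunit, was the only one of 1014 to pass, with a log2 ratio of -6.90 ± 1.01 (SE, n = 3; limma adjusted p = 0.0044). Its normalized ratios were -10.39, -8.44 and -1.88 on the 3 arrays, beside -5.06, -4.33 and -0.39 from raw intensities. Their SD was 4.46, a scatter that the moderated SE does not show. Its spot lies directly beside a GAM control spot in row 1 of the grid, and its Cy3 intensity of 52545 on RPMI8226 replicate 1 and 50174 on replicate 2 stood against 597 on replicate 3, while its Cy5 intensity on replicates 1 and 2, 1573 and 2489, was close to the empty-spot medians of 1570 and 2497, so the normalized values rest on the background correction and the loess curve and are not a measured fold. In total 0 probes were higher and 1 was lower, and 37 had an unadjusted p under 0.05, or 3.65%. Of 289 spots labelled empty that met the same brightness filter, 1 passed when tested alike. The ATP8B2 call was lost, among other alternatives, with all gene probes tested, with the deposited ratios, with all 6 arrays or the repeated scan counted as RPMI8226/R5, and with the RPMI8226 arrays alone. Leaving out either RPMI8226/R5 array gave that same last result. Over all alternatives, kept or lost, its adjusted p ranged from 6.16e-74 (without RPMI8226 replicate 3) to 0.990, and counts were 4 without RPMI8226 replicate 3 and 2 without RPMI8226 replicate 1 or 2. With 2 arrays of the line left, the lowest value rests on the spread that the fit borrows from other probes. It is therefore no measure of the strength of evidence.

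The probe labelled MET had a log2 ratio of 0.07 ± 0.21 (SE, n = 3) in RPMI8226 and that for HGF, its ligand, 0.20 ± 0.20. Values were -0.35 ± 0.23 for ABCB1, a multidrug efflux pump, and 0.02 ± 0.23 for FNTB, the beta subunit of farnesyltransferase; these 4 did not pass the filter and come from the fit of all gene probes. SDC1, which encodes the plasma cell marker syndecan-1, had -0.65 ± 0.31 (limma adjusted p = 0.693), with values from -0.70 to -0.62. Of the MET and HGF list, 0 of 15 measured members passed, also when adjusted over the list alone. Of 23 endoplasmic reticulum chaperone and unfolded protein response genes, 0 passed over all probes and 1 when adjusted over the list alone, HSPA5, an endoplasmic reticulum chaperone, at -1.35 ± 0.27 (limma adjusted p = 0.944 over all probes). RELB, an NF-kappaB subunit, had -0.75 ± 0.21 (limma adjusted p = 0.944). None of the 28 lists passed the test for a shift (camera, smallest adjusted p = 0.755, with 0 lists at an unadjusted p under 0.05).

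The second comparison asked the same in RPMI8226/R5, where no probe passed the limma test (0 higher and 0 lower of 1014; 186, or 18.3%, at an unadjusted p under 0.05). The smallest p-values belonged to SGMS1, a sphingomyelin synthase, at -1.74 ± 0.40 (SE, n = 2; limma adjusted p = 0.265), ATP8B2 at -5.06 ± 1.24, METTL3, the catalytic subunit of an RNA methyltransferase, at 1.45 ± 0.42, HTATSF1 at -1.68 ± 0.49 and COX4I2, a cytochrome c oxidase subunit isoform, at -1.72 ± 0.50. HTATSF1 and COX4I2 rest mainly on RPMI8226/R5 replicate 2, with -2.94 and -3.06 there against -0.41 and -0.38 on replicate 3 (SD 1.79 and 1.90). METTL3 had 0.90 on replicate 2 and 2.01 on replicate 3. ATP8B2 had normalized ratios of -3.62 and -6.50, beside -1.78 and -5.30 from raw intensities. Its Cy5 intensities of 3092 and 375 lay below the empty spots' 95th percentiles of 3426 and 445, so its value is not a measured fold here either. Spots labelled empty, which should hold no gene, had 9.25% at an unadjusted p under 0.05 in the same model, beside 10.7% of all gene probes, and of the 289 empty spots that met the brightness filter 16.6% did, with 3 past the adjusted threshold. With RPMI8226/R5 replicate 3 left out, 366 probes passed, 363 of them lower, on 1 array of the line, which is then assumed to vary like the other line; 2 passed without any one RPMI8226 array.

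Values in RPMI8226/R5 were -0.13 ± 0.26 for MET, 0.20 ± 0.25 for HGF, -0.60 ± 0.28 for ABCB1, -0.37 ± 0.38 for SDC1 and 0.26 ± 0.29 for FNTB (SE, n = 2). The arrays differed widely, with ABCB1 at -1.17 and -0.03 and SDC1 at -0.01 and -0.73 on replicates 2 and 3, and MET, HGF and FNTB on either side of 0. The lowest list p-values were those of the erythroid and platelet markers and of the p53 targets. Of the erythroid and platelet markers 6 of 6 members were above 0, with a median log2 ratio of 0.29. Of the p53 targets 4 of 19 were above 0, with a median of -0.35. Each list had a camera adjusted p = 0.262, and adjusted p = 0.859 with an estimated correlation. Among the p53 targets, 0 passed over all probes and 3 when adjusted over the list alone. ZMAT3, an RNA-binding p53 target, had -1.90 ± 0.26, BTG2 had -0.85 ± 0.24 and SESN2, a stress-response gene also in the ATF4 list, had -0.94 ± 0.27 (limma adjusted p = 0.364 for each). Other members of smallest p were CYP1B1, a target of the aryl hydrocarbon receptor, at -1.74, DNAJB1, a heat shock cochaperone, at -1.12, VEGFA at -1.38, ALDOC at 0.85, NPC1 at -1.22, RPL13 at -1.37 and SCD at -1.40. Markers of other cell types gave FCGR1A at -1.80, S100A8 at -1.35 and KRT8 at -1.55. For most of these, RPMI8226/R5 replicate 2 carried the mean: on replicates 2 and 3 CYP1B1 had -2.73 and -0.74, DNAJB1 -1.56 and -0.68, VEGFA -2.31 and -0.44, NPC1 -1.87 and -0.57, RPL13 -2.26 and -0.49, SCD -2.44 and -0.35, FCGR1A -2.68 and -0.93, S100A8 -2.15 and -0.55, KRT8 -2.55 and -0.56, and SESN2 -1.42 and -0.46. ZMAT3 had -1.71 and -2.09, but its normalized log2 Cy3 intensity was 13.49 on RPMI8226/R5 replicate 3 against 7.79 on replicate 2. None of these passed over all probes (limma adjusted p = 0.364 for each). Adjusted over the list alone, 1 of 9 aryl hydrocarbon receptor targets (CYP1B1), 2 of 11 heat shock genes (DNAJB1, and HSPA6 at -1.09), 2 of 13 myeloid markers (FCGR1A and S100A8) and 2 of 9 B cell markers (PAX5 at -0.81 and CD79B at -0.85) passed, and 0 in each of these lists over all probes. HSPA6, PAX5 and CD79B were named after their values were seen, and had -1.64, -1.16 and -1.15 on replicate 2 against -0.54, -0.45 and -0.55 on replicate 3. The median of the 15 MET and HGF list members was 0.08 and their mean -0.03, of opposite sign.

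**Figure D2:**
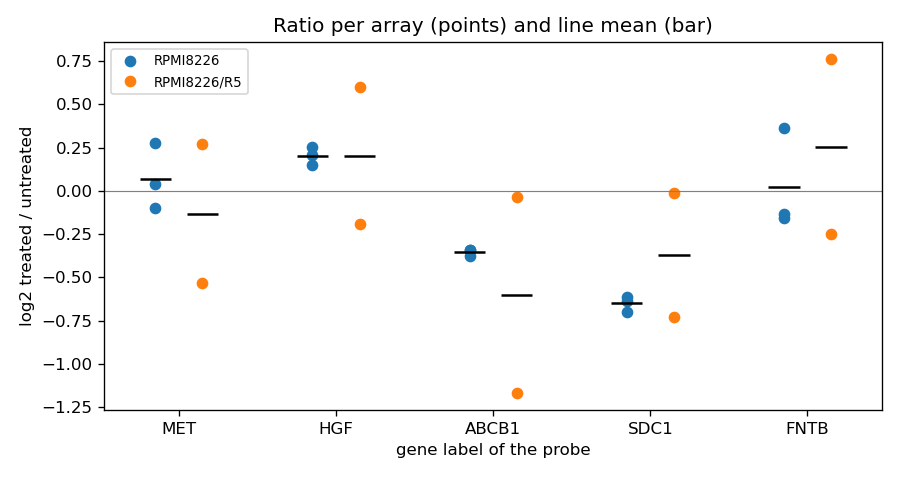
Log2 ratio of treated to untreated intensity for probes labelled MET, HGF, ABCB1, SDC1 and FNTB, with a point per array and a bar at each line's mean (3 arrays of RPMI8226, 2 of RPMI8226/R5). For MET the RPMI8226/R5 arrays lie at -0.53 and 0.27, on either side of 0.

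The third comparison asked whether the response differed between RPMI8226 and the multi-resistant line RPMI8226/R5. No probe passed the limma test of the difference, RPMI8226/R5 minus RPMI8226 (0 higher and 0 lower of 1014; 8 at an unadjusted p under 0.05). The largest departures by p were SGMS1 at -1.53 ± 0.51 log2 units, METTL3 at 1.56 ± 0.55, UBE2K, a ubiquitin-conjugating enzyme, at 1.41 ± 0.55, CHRND at 1.19 ± 0.49 and VRK2, a kinase, at 1.41 ± 0.60 (SE, 3 against 2 arrays; limma adjusted p = 0.998 for each). Without RPMI8226/R5 replicate 3 these values were 1.00 for METTL3, 0.79 for UBE2K, 0.77 for CHRND and 0.58 for VRK2, and without replicate 2 SGMS1 was -1.05. On RPMI8226 replicate 3, METTL3 had 0.61, UBE2K 0.62 and VRK2 0.79, against values below 0 on replicates 1 and 2. For VRK2 this exceeded the 0.53 of RPMI8226/R5 replicate 2. CHRND had -0.25 on RPMI8226 replicate 3, but its normalized log2 Cy3 intensity there was 14.01, against 9.20 to 10.66 on the other arrays. Of the 289 empty spots, 1 passed the same test. The difference was -0.20 ± 0.33 for MET, 0.0019 ± 0.32 for HGF, -0.25 ± 0.37 for ABCB1, 0.28 ± 0.49 for SDC1 and 0.23 ± 0.37 for FNTB. From the lists, ZMAT3 had -2.04 ± 0.33, FCGR1A -2.09 ± 0.56, RPL13 -1.63 ± 0.49, DNAJB1 -1.43 ± 0.36 and NPC1 -1.39 ± 0.41 (limma adjusted p = 1.00 for each). Adjusted over the list alone, 1 p53 target (ZMAT3) and 1 heat shock gene (DNAJB1) passed, and 0 over all probes. In RPMI8226/R5, FCGR1A, RPL13, DNAJB1 and NPC1 were each further below 0 on replicate 2 than on replicate 3, as given above. ZMAT3 had a normalized log2 Cy3 intensity of 13.49 on RPMI8226/R5 replicate 3 against 7.79 on replicate 2. Without RPMI8226 replicate 3, 1 probe passed the test of the difference. No list passed the test for a difference (0 of 28 by camera). The 1 list at an unadjusted p under 0.05 was that of the erythroid and platelet markers, upward (camera adjusted p = 0.707).

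The mean log2 ratios of the lines correlated across the 1014 probes with r = 0.60, and across all gene probes with r = 0.31. Across all spots labelled empty r was 0.35, which stands beside the all-probe value. No such value was computed for empty spots that met the brightness filter, so the 0.60 has no matching control. The 0.60 also includes the ATP8B2 probe, at -6.90 and -5.06. Probes are not independent replicates, and because all arrays share one dye orientation, a dye effect particular to a spot adds to such values. Between arrays, Spearman's correlation of the log2 ratio over all gene probes was 0.17 for RPMI8226 replicates 1 and 2, -0.0042 for 1 and 3, 0.10 for 2 and 3, and 0.0903 for the pair of RPMI8226/R5 arrays. Of the 6 pairs of distinct scans from different lines, some reached higher values, 0.31 for RPMI8226 replicate 3 with RPMI8226/R5 replicate 3, 0.28 for RPMI8226 replicate 1 with RPMI8226/R5 replicate 2 and 0.24 for RPMI8226 replicate 2 with RPMI8226/R5 replicate 2, and the others lay between 0.0593 and 0.0951. At empty spots those higher pairs reached 0.35, 0.31 and 0.26. Over the 1014 tested probes the values differed, with 0.41 for the RPMI8226/R5 pair, -0.0083 for RPMI8226 replicates 1 and 2, 0.17 for 1 and 3 and 0.091 for 2 and 3, and across lines 0.55 for both replicates 3 and 0.49 for RPMI8226 replicate 3 with RPMI8226/R5 replicate 2. The repeated scan gave 0.99.

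**Figure D3:**
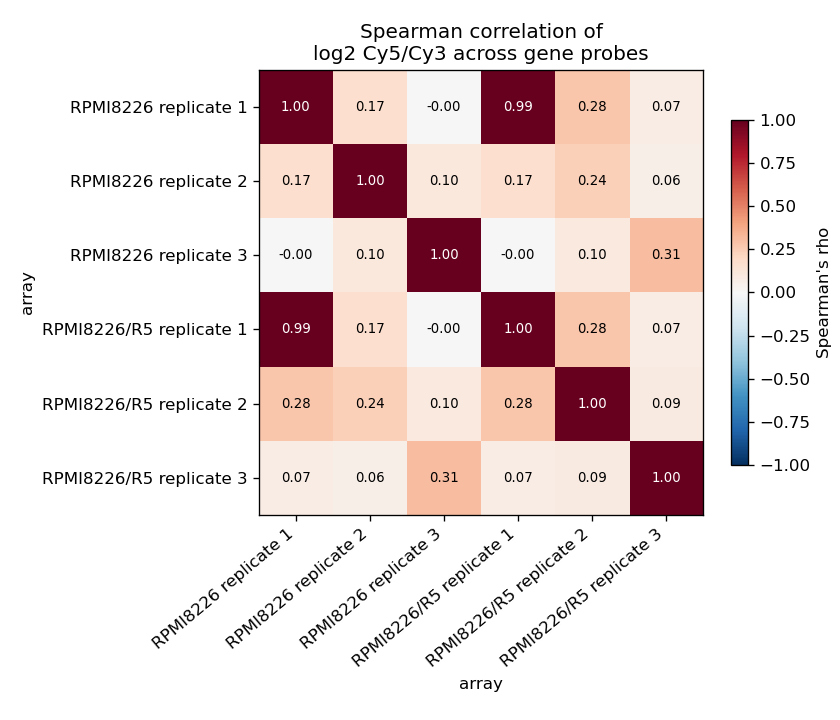
Spearman correlation of the log2 Cy5 to Cy3 ratio across all gene probes for each pair of the 6 deposited arrays. The repeated scan, RPMI8226 replicate 1 and RPMI8226/R5 replicate 1, reaches 0.99, and the next highest pair, RPMI8226 replicate 3 with RPMI8226/R5 replicate 3, reaches 0.31 across the lines.

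The fourth comparison set untreated RPMI8226/R5 against untreated RPMI8226 in the Cy3 channel. No probe passed the limma test (0 higher and 0 lower of 1014; 15 at an unadjusted p under 0.05). The smallest p-values were those of RBMS1 at 0.94 ± 0.33, LRMDA at 1.09 ± 0.39, KDM5B, a histone demethylase, at 1.42 ± 0.52, CHCHD4, a mitochondrial import factor, at -2.28 ± 0.84 and HNRNPA0 at 0.87 ± 0.33 (log2 units, RPMI8226/R5 minus RPMI8226, SE, 3 against 2 arrays; limma adjusted p = 0.976 for each). ABCB1 had 0.52 ± 0.35, MET -0.32 ± 0.40, HGF 0.51 ± 0.33, SDC1 1.03 ± 0.59 and FNTB 0.36 ± 0.74. Single arrays carried much of several values: on leaving out each array FNTB ranged from -0.99 to 1.71 and MET from -0.69 to 0.036, SDC1 was 0.46 without RPMI8226 replicate 2, and without RPMI8226/R5 replicate 3 KDM5B was 0.79, LRMDA 0.60, HNRNPA0 0.52 and ABCB1 0.27. CHCHD4 had normalized log2 Cy3 intensities of 8.51, 10.94 and 11.33 on RPMI8226 replicates 1, 2 and 3, against 8.12 and 7.85 in RPMI8226/R5. Its value thus rests mainly on RPMI8226 replicates 2 and 3. List members of smallest p were PHLDA1 at 1.42, SESN1 at 1.29, TRAF1 at -1.35, CANX at -1.36, ITGB1 at -1.18, FLCN at -1.12 and TXNIP at -1.06 (limma adjusted p = 0.436 for each). Adjusted over the list alone, PHLDA1 among immediate early genes, TRAF1 among NF-kappaB genes and SESN1, a member of both the p53 and the FOXO target lists, passed, and 0 over all probes. In this fit of all gene probes 3529, or 11.4%, had an unadjusted p under 0.05. Empty spots were not tested in this comparison, so that share has no control. No list passed the test for a shift (0 of 28 by camera). The 2 lists at an unadjusted p under 0.05 were hypoxia and glycolysis genes, upward, and ribosomal protein genes, downward. Both had a camera adjusted p = 0.597, and adjusted p = 0.917 with an estimated correlation. The lines were never on one array, so differences between arrays are part of these values.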

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

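The tests of this part were chosen after the result had been seen. Among the spots labelled empty, which serve the comparisons only as background, 33 of 7156 were locally bright on at least 4 of the 5 distinct scans, where 0.0527 would be if scans were independent. Among gene probes 159, or 0.513%, were, beside 0.461% of the empty spots.

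Labels shifted, mirrored or turned as a whole are argued against by the control spots: 150 of 151 spots labelled GAM or Cy3 control (99.3%, 95% exact binomial interval 96.4% to 100.0%) were bright in Cy3 as labelled, against at most 87.4% under 6009 such changes. Labels transposed within blocks, or block columns in reverse order, cannot be told apart from the labels as given by these spots, because both leave them on bright positions (99.3%). The mean percentile rank of local brightness, gene probes minus empty spots, was -4.10 as labelled. Its highest value was 4.57 over 6000 shifts of the label list and 0.784 over 11 mirrored, turned or transposed labels. Each is the maximum of many tries and was not tested, so it does not decide whether the labels are right. Weak or failed hybridisation under correct labels stays open too. The odds ratio of bright spots, gene probes over empty spots, was 1.11 (two-sided Fisher's exact p = 0.643), and contaminated printing wells could recur at empty positions as well. No biological explanation was tested.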

How the results depend on the processing

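Counting the repeated scan once, counting it as RPMI8226/R5 and removing spatial trends were chosen after seeing the data. The set of all 6 arrays was the planned one, kept here as an alternative on the probes of the main fit. Plain background subtraction and a slide batch were not run, as the files give neither local backgrounds nor a slide holding over 1 array. For RPMI8226 the 1 call became 0 with the deposited values, no filter, array weights, an intensity trend, that line's arrays alone, all 6 arrays or spatial trends removed. It became 2 to 4 on leaving out an RPMI8226 array (4 without replicate 3, 2 without replicate 1 or 2). Leaving out either RPMI8226/R5 array gave the same RPMI8226 result as that line's arrays alone, since 1 array adds nothing to the spread. These are thus not separate losses of the call among the 10 given below for ATP8B2. With the repeated scan counted as RPMI8226/R5, RPMI8226 kept a count of 1, but ATP8B2 did not pass. For RPMI8226/R5 the 0 calls became 2 with median centring, 1 with that line's arrays alone or the repeated scan counted there, and 0 to 366 on leaving out each array (366 without RPMI8226/R5 replicate 3, 2 without any one RPMI8226 array). For the difference they were 0 to 1 (1 without RPMI8226 replicate 3). The lines' correlation of 0.60 became 0.67 with no background correction, 0.52 with median centring, 0.37 with deposited values and 0.31 with no filter. In no list setting did a list pass. With median centring 1 probe was lower in both lines, where 0.00197 would be under independence. That expectation does not hold for a dye effect particular to a spot, since all arrays share one layout and dye orientation, so it is no measure of a shared response. The cause of the changes between settings was not tested. In raw intensity a gene probe was brighter than an empty spot with a probability of at most 0.499, and of at most 0.522 in net intensity, which limits what these values can show.

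With the replicate block, calls numbered 3 for RPMI8226, 2 for RPMI8226/R5, 0 for the difference and 6 for the untreated lines. Only 2 numbers are shared by distinct scans. Deviations from the line means correlated at 0.055 and 0.14 for same-numbered arrays, which a line with 2 arrays mirrors in the others, so these correlations do not establish pairing. They do not exclude it either. Both arrays numbered 3 were the dimmest scans, with Cy5 medians of gene probes of 286 and 315 against 1544 to 2409 on the others. Their ratios also correlated most among distinct scans, at 0.31 over all gene probes. A batch shared by these arrays remains possible.

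Of 946 values of named genes under alternatives, 905 kept their sign, of which 864 kept their side of the threshold, 31 came to pass and 10, all of ATP8B2 in RPMI8226, no longer passed; none of the 41 that turned passed before or after. In RPMI8226, MET turned to -0.25 (median centring), -0.38 (deposited values) and -0.030 (repeated scan counted as RPMI8226/R5), with -0.030 to 0.16 on leaving out arrays; HGF to -0.40 (median centring) and -0.17 (deposited values); FNTB to -0.11 (spatial trends removed), -0.15 to 0.12 on leaving out arrays. In RPMI8226/R5, MET turned to 0.0034 with all 6 arrays and 0.0034 with the repeated scan counted there (-0.53 to 0.27 on leaving out arrays); HGF to -0.71 (deposited values) and -0.10 (spatial trends removed), -0.19 to 0.60; ABCB1 to 0.49 and FNTB to -0.31 (-0.25 to 0.76) with deposited values; SDC1 to 0.042 with spatial trends removed. For the difference, deposited values gave UBE2K -0.038, CHRND -0.60, VRK2 -0.97, HGF -0.54, ABCB1 0.65 and FNTB -0.48. MET turned to 0.033 (repeated scan counted as RPMI8226/R5), HGF to -0.079 (no background correction) and -0.19 (spatial trends removed), SDC1 to -0.073 and FNTB to -0.14 (median centring). Leaving out arrays gave MET -0.61 to 0.20, HGF -0.39 to 0.40, ABCB1 -0.82 to 0.32, SDC1 -0.078 to 0.64 and FNTB -0.27 to 0.74. For the untreated lines, FNTB turned to -0.15 (replicate block), -0.10 (all 6 arrays) and -0.62 (repeated scan counted as RPMI8226/R5), -0.99 to 1.71 on leaving out arrays, and MET ranged from -0.69 to 0.036.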

Other observations

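The tests in the next 2 paragraphs were written down before their values were seen, except that the pattern each addresses had been noticed first; the test on empty spots that met the brightness filter was added after the result had been seen.

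In RPMI8226/R5, 10.7% of gene probes had an unadjusted p under 0.05. A candidate explanation is array structure that does not depend on the probe, such as position on the slide or dye. Spots labelled empty gave 9.25%, or 0.868 of the share of gene probes, as that explanation needs. Among those meeting the brightness filter the shares were 18.3% of 1014 gene probes and 16.6% of 289 empty spots. In RPMI8226 the all-probe shares were 4.89% and 5.06%. The excess itself depended on the model. Of the 1014 probes, 5.03% had such a p in RPMI8226/R5 with that line's arrays alone, where RPMI8226 with its own arrays alone had 17.9%. With array weights the shares were 0.592% in RPMI8226/R5 and 22.0% in RPMI8226. With spatial trends removed they were 10.4% and 3.06%, so a part of the RPMI8226/R5 share stayed after that step. A response of the cells remains open for what is left, untested.

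The lower ratio at the ATP8B2 probe came from bright Cy3 with Cy5 near background. Light running over from GAM control spots in general is argued against: of 102 other gene or empty spots directly to the right of one, 1 (0.98%, 95% exact binomial interval 0.0248% to 5.34%) exceeded the empty spots' 95th percentile in Cy3 on at least 4 of 5 scans, an interval below the 10% that this explanation was taken to need. A displacement of the grid in that corner alone could still be the source and was not tested; the control to its left read 22132 and 20933 where the probe read 52545 and 50174, and 32554 where it read 597. No other probe carried the name ATP8B2, so lower ATP8B2 RNA after SU11274 stays open, untested.

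Local brightness at gene probes correlated between scans with a median Spearman's rho of 0.219 over 20 pairs of scans and dyes, and at empty spots with 0.216.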
